A study of Mus musculus with 7 samples.

How the data were processed

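Lens epithelial cells of 1-month-old wild-type and connexin 50 knockout mice were profiled by droplet single-cell RNA sequencing of transcript 3′ ends (10x Genomics, v3.1 chemistry per the labels' protocols). Per the same protocols, lenses were treated with trypsin, and the peeled capsules with dispase and a trypsin substitute, before the suspended cells were loaded. The titles list 4 wild-type and 3 knockout samples, whereas the protocol speaks of cells pooled from 3 wild-type and 4 knockout littermates. The genotype label of the wild-type samples gives a strain name, and the number in that name differs from sample to sample. Whether the animals themselves differed in strain is not known.

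The deposited values were counts, with 1 combined matrix of unique molecular identifiers (UMIs) per gene and cell for each genotype. The authors made these counts with Cell Ranger 2.2.0 on the mouse build GRCm38 (mm10), per the submitters' processing notes, and per the file headers the software version was 3.0.2. Neither source says which version made which step. No column or barcode suffix in the matrices tied a cell to an animal, so each matrix was treated as 1 library. The wild-type matrix held 2513 barcodes with 20430480 UMIs and the knockout matrix 2609 barcodes with 14658568 UMIs, over 31053 genes. The lowest total of a barcode was 500 UMIs.

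Barcodes with at least 500 detected genes and at most 15% mitochondrially encoded UMIs were retained. This removed 650 wild-type and 480 knockout barcodes with few genes, and a further 19 and 6 for their mitochondrial share. Scrublet, as implemented in scanpy 1.11.5 and run on each library, called 23 wild-type cells (1.25%) and 19 knockout cells (0.895%) as doublets, and these were left out. The 1821 wild-type and 2104 knockout cells that remained had medians of 8955 and 6078.5 UMIs. They were clustered together with the Leiden algorithm (leidenalg 0.10.2, resolution 0.6) on a graph of 15 nearest neighbours in 30 principal components of 2000 variable genes. Values were log-normalized to 10000 UMIs per cell and centred per gene within each library.

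Each cluster was placed on an epithelial, fibre or cycling side by the list of fixed markers (lens epithelial, lens fibre, cycling) with the highest median log2 fold against all other cells, at a pseudocount of 20 CPM (the usual depth-scaled unit of counts). That rule was chosen after the clusters had been seen. The marker lists themselves, the gene lists and the rule for naming genes were fixed before the data were examined. The name "lens epithelial-like" was not used, because cluster 4 had a corneal marker (Aldh3a1) and no lens epithelial marker among its 10 leading genes. Clusters 1, 2, 3, 5 and 6 also had no lens epithelial marker among theirs, and no marker of another cell type. Comparisons therefore used all clusters outside the fibre side, here called the non-fibre clusters and numbered 1 to 6, 10 and 11. This pool was chosen after the clusters had been seen. The rule fixed beforehand asked for lens epithelial-like cells, or for all retained cells if no cluster could be named so. All retained cells would have given 10 of the same 12 genes with the highest and 10 of the same 12 with the lowest ratios, and their other values are given as an alternative.

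UMIs of the 1288 wild-type and 1892 knockout cells of the non-fibre clusters were summed per library and scaled to CPM. With 1 library per genotype there was no replicate and no test. Levels are given with exact Poisson intervals, ratios with exact conditional intervals and shares of cells with exact Clopper-Pearson binomial intervals, all at 95%. They cover counting error only and say nothing of the spread between animals. The median gene with at least 100 UMIs had a log2 ratio of knockout to wild-type CPM of 0.14. Log2 ratios below are given relative to that median unless they are said to be of CPM. A gene with 0 UMIs in 1 library was set against a floor of 3 UMIs in that library.

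The rule for named genes took genes of the labels, here Aqp1, first. It then took the 12 highest and the 12 lowest ratios, ranked by the interval bound nearest to 1, among genes with at least 100 UMIs over both libraries, leaving out mitochondrially encoded, ribosomal protein and sex-linked genes. From each gene list whose median lay outside the central 95% of 10000 random lists, up to 4 members with at least 50 UMIs and the largest log2 ratios were named, and so was every listed connexin and aquaporin with at least 50 UMIs. Some genes that the rule takes are not reported here. The random lists had the same size and were matched on mean expression in 20 bins. List members needed at least 20 UMIs. For shares of cells with a UMI, each cell was thinned to 3000 UMIs, which left out 103 wild-type and 84 knockout cells of the non-fibre clusters and 26 and 19 of the fibre side.

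Coordinates are from the GENCODE vM21 annotation of GRCm38, in which 31011 of the 31053 gene identifiers were found. Near-identical copies of a gene were sought with BLAST 2.17.0 between the last 600 bases of annotated transcripts, as matches of at least 100 bases at 95% identity or more. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

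The steps were tested on simulated data, with counts drawn for the comparison of knockout and wild-type non-fibre clusters over 8733 genes. The 95% intervals held the true ratio for 95.9% of genes. All 50 genes planted at 4-fold and all 50 at 0.25-fold passed the 2-fold limit, and 0 of 8533 unchanged genes did. Of 400 lists of genes picked at random, planted genes not barred, 5.75% fell outside the central 95%. The simulation had counting error only, so it does not show how often animals of a genotype would differ as much. Its genes were also drawn independently of each other. It therefore does not show how often lists of genes that vary together would fall outside.

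Alternatives covered the barcode filter, the doublet calls, the scaling, the minimum of UMIs, the averaging over cells, the choice of cells, the centring and resolution of the clustering, and the thinning. The planned weighting of all clusters to equal shares was not run, since most clusters had too few cells of 1 library. A form limited to clusters with at least 20 cells of both was used instead. In that form, here called the cluster weighting, both libraries were given the same mix of clusters. Each cluster counted by its number of cells in both libraries together. Barcodes removed by the filter or as doublets were left out of the main comparisons.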

Results

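Single-cell transcriptomes of the lens epithelium were compared between wild-type and connexin 50 knockout mice at 1 month of age. The lens epithelium is the single layer of cells under the anterior capsule that divides and, at the lens equator, differentiates into fibre cells. The data were 1 combined matrix per genotype, each treated as 1 library. After filtering, the wild-type library held 1821 cells with a median of 8955 UMIs and 1995 genes, and the knockout library 2104 cells with a median of 6078.5 UMIs and 1816 genes. Because each genotype was 1 library, no difference below has a replicate check, and every interval covers counting error only.

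The first question was the level of Aqp1, a water channel of the plasma membrane that is named in the title of the series. Aqp1 (ENSMUSG00000004655, chromosome 6, 55336432 to 55348555, plus strand, GRCm38) was at 83.0 CPM in the wild-type non-fibre clusters (922 UMIs, 95% interval 77.7 to 88.5) and at 290 CPM in the knockout ones (3361 UMIs, 280 to 300). Its log2 ratio was 1.66 (1.55 to 1.77). In the thinned cells, 19.3% of wild-type (17.1% to 21.7%) and 51.2% of knockout non-fibre cells (48.8% to 53.5%) had an Aqp1 UMI, and without thinning 35.6% and 69.6% did. Fibre-side cells, which had almost no Aqp1, gave thinned shares of 0.789% in the wild type and 4.15% in the knockout. Median depths before thinning were 8754 and 6024.5 UMIs in the non-fibre cells and 11873 and 8415.5 UMIs on the fibre side.

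Within the wild-type library, Aqp1 ran from 26.3 CPM in cluster 2 and 69.7 CPM in cluster 4 to 136 CPM in the dividing cells of cluster 10 and 147 CPM in cluster 5. Within the knockout library it was at 289 CPM in cluster 1, 310 CPM in cluster 3 and 259 CPM in cluster 6. In the 3 non-fibre clusters with at least 20 cells of both libraries, the log2 ratio of Aqp1 CPM was 3.15 (2.76 to 3.55) in cluster 2, 2.38 (1.92 to 2.81) in cluster 4 and 1.33 (0.93 to 1.74) in cluster 10. Cluster 2 held 79 and cluster 4 held 33 knockout cells.

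**Figure D1:**
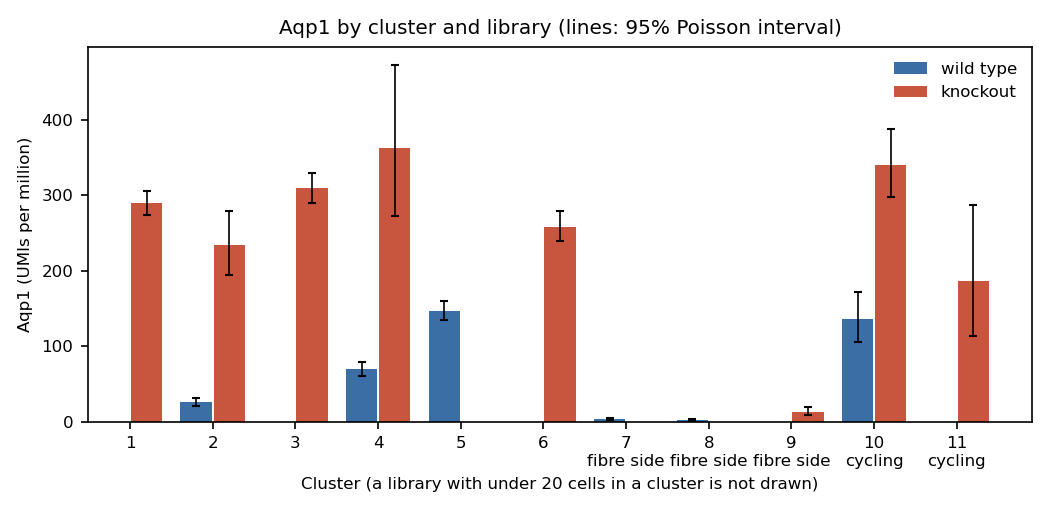
Aqp1 in CPM (vertical axis) by cluster (horizontal axis), for each library with at least 20 cells in it, with wild-type cells in blue, knockout cells in red and lines for the 95% Poisson interval. Aqp1 lay between 1.75 and 147 CPM across the wild-type clusters drawn and at 186 CPM or more in every knockout cluster drawn outside the fibre side.

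The lists of connexins and of other aquaporins were measured next. Of the connexins, Gja1 (connexin 43) had a log2 ratio of 0.75 (0.65 to 0.85), from 109 to 203 CPM. Gja3 (connexin 46) had 0.45 (0.38 to 0.51). Gjc1 had 0.18 (-0.22 to 0.58), an interval that includes the median gene. The 4 measured genes of the connexin list, which also holds pannexin 1, had a median of 0.60, at percentile 92.9 of like lists. Of the aquaporins, Aqp5 had -0.77 (-1.10 to -0.44). The intervals of Mip (0.07, -0.01 to 0.15), Aqp4 (-0.00, -0.20 to 0.19) and Aqp11 (-0.04, -0.76 to 0.70) included the median gene. The 5 measured aquaporins had a median of -0.00, at percentile 60.9.

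The next question was how cells fell into clusters. Joint clustering gave 11 clusters, of which 8 had at least 90% of their cells from 1 library and together held 84.0% of all cells. Clusters 1 (13 wild-type and 779 knockout cells), 3 (0 and 463) and 6 (5 and 414) were almost wholly of the knockout library. Clusters 4 (419 and 33) and 5 (411 and 15) were almost wholly of the wild-type library, and cluster 2 had 385 and 79 cells. A cluster mostly of 1 library may be that library and not a type of cell, so the sizes are not compared between genotypes. This split also depended on the settings: the share of cells in such clusters was 38.7% after thinning to 3000 UMIs and 44.4% without the barcode filter.

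**Figure D2:**
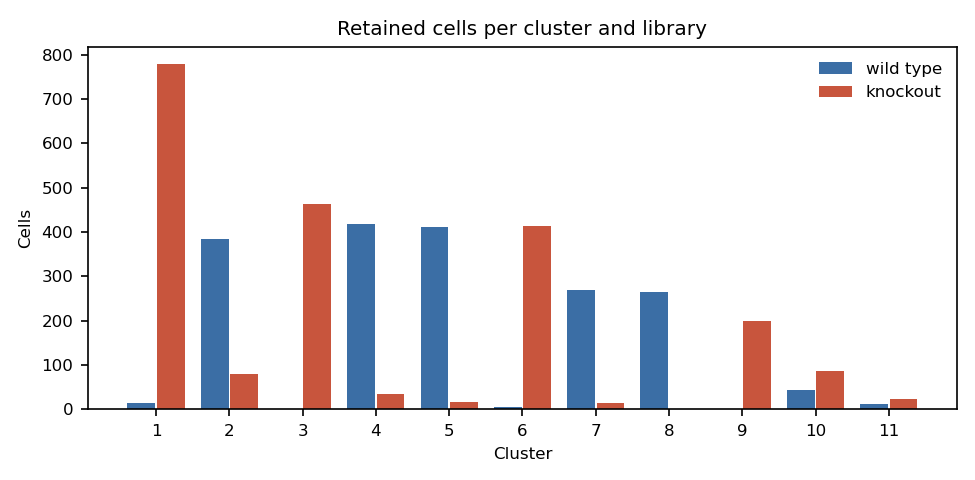
Number of retained cells (vertical axis) in each of the 11 clusters (horizontal axis), wild type in blue and knockout in red. Cluster 3 held 463 knockout and 0 wild-type cells, whereas cluster 10 held 44 wild-type and 87 knockout cells.

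The leading genes of cluster 1 were Frat2, Eef2, Socs3, Egr2 and Maff, those of cluster 3 Mt2, Ccl2, Mt1, Cxcl10 and Ccl7, and those of cluster 6 Notch2, Slc39a1, Kdm6b and Spry2. Cluster 2 was led by R3hdml, Hspa1a, Hspa1b and Ptgds, cluster 4 by Olfml3, Pdpn and F2r, and cluster 5 by Ndufa4l2, Ace and Krt19. Clusters 7 (269 and 13 cells), 8 (264 and 0) and 9 (0 and 199) lay on the fibre side, with crystallin genes such as Crygn and Cryba2 among their leading genes. Cluster 8 also had the fibre markers Mip and Lim2, and cluster 9 Lim2 and Mip. Cluster 7 had a Schwann cell marker (Pmp22) and no fixed fibre marker among its 10 leading genes. The fibre side took 533 of 1821 wild-type cells (29.3%, 27.2% to 31.4%) and 212 of 2104 knockout cells (10.1%, 8.82% to 11.4%). No direction is read from these shares, which the peeling of the capsule can set.

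Clusters 10 and 11, led by Top2a, Rrm2 and Birc5 and by Cenpf and Cenpa, held the cycling cells. They made up 3.02% of all retained wild-type cells (55 cells, 2.28% to 3.91%) and 5.18% of all retained knockout cells (109 cells, 4.27% to 6.22%). These totals include fibre-side cells, whose share differed between the libraries, so no direction is read here either. Of the non-fibre cells alone, 55 of 1288 wild-type and 109 of 1892 knockout cells lay in these clusters. In a count of mitotic transcripts per cell, the planned limit of 2 UMIs gave no difference detectable at this depth. The share of thinned non-fibre cells with at least 2 UMIs of the G2M list was 4.22% in the wild type (3.15% to 5.53%) and 4.98% in the knockout (4.02% to 6.08%), with overlapping intervals, and without thinning it was 8.15% and 8.14%. With at least 1 UMI, 141 of 1185 thinned wild-type cells (10.1% to 13.9%) and 271 of 1808 knockout cells (13.4% to 16.7%) counted, 3.09 points more in the knockout. A count with the S phase list, which was not among the planned comparisons, differed. In thinned cells 13.1% of wild-type (11.2% to 15.1%) and 28.8% of knockout cells (26.7% to 31.0%) had at least 2 of its UMIs, and without thinning 45.0% and 53.8% did. Free RNA can add to such counts, so no share of dividing cells is read from them.

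The transcriptomes of the non-fibre clusters were then compared gene by gene. Of 8765 genes with at least 100 UMIs, 1145 were at least 2-fold higher in CPM in the knockout library and 144 had a CPM ratio of 1/2 or less. Scaled to the median gene, the numbers were 910 and 226. In 376 cells per library matched on their share of UMIs from immediate early genes, 377 genes were higher and 114 lower in CPM by the same limits, of 4360 with at least 100 UMIs. This matching was not among the planned comparisons, and with fewer cells it tests fewer genes. These counts describe the libraries and are not counts of genes changed by genotype.

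The 12 highest ratios were not tested for a shared function. Klf2, a transcription factor, went from 4.32 to 194 CPM, a log2 ratio of 5.35 (4.93 to 5.79). Mt2, a metallothionein that binds zinc and copper, went from 28.6 to 672 CPM, with a log2 ratio of 4.41 (4.25 to 4.58). Trib1, a pseudokinase, had 4.29 (4.07 to 4.52). The cytokine gene Il6 had 2 wild-type and 149 knockout UMIs (6.01, 4.13 to 9.07) and the interferon-inducible GTPase gene Iigp1 had 1 and 123 UMIs (6.74, 4.23 to 12.05). Emp1 (5.87), Nfatc2 (5.35) and Fscn1 (5.34), the last encoding the actin-bundling protein fascin, had between 5 and 7 wild-type UMIs each. With the cluster weighting their ratios were 2.72, 5.93 and 5.33. Some of the highest ratios were close to presence against absence. Prm1, which encodes the sperm chromatin protein protamine 1 (chromosome 16, 10796326 to 10805839), had 0 wild-type and 301 knockout UMIs. It was at least 86.9-fold higher against the floor of 3 UMIs, and the log2 interval began at 6.13. The labels do not describe the knockout construct, so whether these UMIs come from the Prm1 locus is not known. Htr1d, a serotonin receptor gene, had 1 and 254 UMIs (7.78, 5.29 to 13.09). The noncoding RNA Gm17300 had 0 and 167 UMIs and was at least 48.2-fold higher against that floor, with a log2 interval from 5.28. The processed pseudogene Gm10093 had 6 and 519 UMIs (6.23), and its 3′ end matches that of Hdac1, so its counts are uncertain. Summed with Hdac1, the log2 ratio of CPM was only 0.45.

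Among the lowest ratios, Hspa1b, an inducible heat shock protein gene, had 436 wild-type and 6 knockout UMIs, a log2 ratio of -6.39 (-7.84 to -5.26). With the cluster weighting its ratio was -3.19. Olfml3, which encodes a secreted olfactomedin-like protein, went from 834 to 118 CPM (-2.97, -3.05 to -2.89). Pacs2, which encodes a sorting protein of the endoplasmic reticulum and mitochondria, had 1329 and 107 UMIs (-3.84, -4.14 to -3.56). Rpgrip1 had 100 and 2 UMIs (-5.85, -8.92 to -3.96), Trim12a 117 and 3 (-5.49, -7.79 to -3.91) and Rflna 133 and 15 (-3.36, -4.23 to -2.58). E030030I06Rik had 118 and 1 UMIs (-7.09, -12.40 to -4.58) and the antisense transcript 4930481A15Rik 160 and 14 UMIs (-3.72), a count that is uncertain because the use of strand in the counting is not stated. The noncoding RNA AC123059.1 had 125 and 0 UMIs and was at least 48.1-fold lower against the floor, with a log2 interval up to -5.27. Rnaset2b had 1183 and 44 UMIs (-4.96) and the histone gene Hist1h2ap 418 and 35 UMIs (-3.78). Both share near-identical 3′ ends with other genes, Rnaset2b with Rnaset2a and Hist1h2ap with 10 histone genes, so their counts are uncertain. Summed with these copies, the log2 ratio of CPM was -0.21 for Rnaset2b and still -2.87 for Hist1h2ap.

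**Figure D3:**
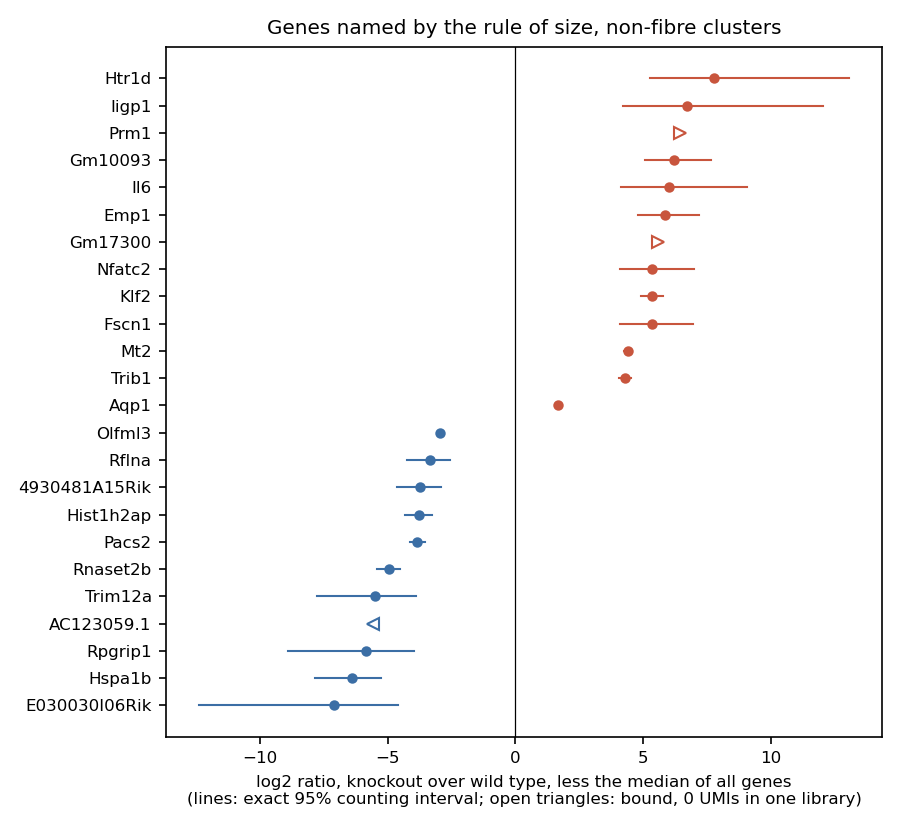
Log2 ratio of knockout to wild-type CPM relative to the median gene (horizontal axis) for the genes named by the rule of size (vertical axis), with lines for the exact 95% counting interval and open triangles for bounds where 1 library had 0 UMIs. Values run from -7.09 for E030030I06Rik to 7.78 for Htr1d, with Aqp1 at 1.66.

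Of 30 programme lists set against random lists matched on expression, 15 had a median outside the central 95%. Genes of a programme can vary together, unlike genes picked at random, so such lists can fall outside more often than random ones. The list of dissociation-responsive and immediate early genes stood farthest from its random lists, with a median log2 ratio of 1.61 above all 10000 of them. Of its 22 measured members, 19 lay above the median gene. Klf2 was the highest, followed by Socs3 (3.58), a feedback inhibitor of cytokine signalling, and Atf3 (2.64), a stress-induced transcription factor. Hspa1b was the lowest, and Hspa1a (-1.25) also fell, while Hspa8 lay at the median gene within its interval. The list took 1.01% of wild-type and 3.001% of knockout UMIs. Feedback inhibitors and targets of the FGF and ERK pathway were also high, with 10 of 13 members above the median gene and a median of 0.65 (percentile 99.2). The median rested on which members were measured: in CPM it was 0.79, against 1.57 for members with at least 50 UMIs and 3.16 for those with at least 200. They included the phosphatase genes Dusp5 (3.58) and Dusp6 (3.43), Spry2 (3.25) and Ier3 (3.01). The FGF receptors and ligands had a median of -0.04 over 6 genes.

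Genes of cholesterol synthesis had a median of 0.77, above all 10000 random lists, with 19 of 22 above the median gene. The largest ratios were those of Idi1 (2.58), Insig1 (2.34), Hmgcs1 (2.06) and Sqle (1.98). In the Notch list 11 of 12 members lay above the median gene, with a median of 0.67 (percentile 99.5), led by Notch2 (3.17), Nrarp (2.34), the ligand gene Jag1 (1.99) and Lfng (0.81). The BMP list had a median of 0.69 (percentile 99.3), 7 of 9 members above the median gene, and its largest ratios in the target genes Id4 (1.76), Id1 (1.59), Smad6 (1.28) and Id3 (0.79). For adherens and tight junctions and Eph signalling, 13 of 16 genes lay above the median gene, with a median of 0.59 (percentile 99.8), among them Efna5 (1.15), Cldn12 (1.11), Epha2 (1.10) and Ctnna1 (0.82). Genes of ion and solute transport had a median of 0.25 (percentile 98.2), 17 of 24 above the median gene, with the amino acid transporter Slc7a5 at 1.60, the lactate transporter Slc16a1 at 1.26 and the glucose transporter Slc2a1 at 1.08.

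The S phase list had a median of 0.43 (percentile 98.3), with 18 of 22 genes above the median gene. Its largest ratios belonged to the replicative helicase genes Mcm4 (2.57), Mcm2 (2.18), Mcm6 (1.67) and Mcm3 (1.65). The G2M list had a median of -0.10 over 25 genes (percentile 7.58). The p53 response list had a median of 0.52 (percentile 98.8), 9 of 14 above the median gene, with Plk2 at 3.05, the cell cycle inhibitor Cdkn1a at 2.01, Mdm2 at 1.57 and Ccng1 at 1.21. The insulin and PI3K list had 0.46 (percentile 98.6), 12 of 17 above the median gene, led by Sgk1 (3.53), Igfbp2 (1.56), Irs2 (1.49) and Akt2 (1.42). The YAP target list had 0.53 (percentile 98.1), with 5 of 8 above the median gene and its largest ratios in Ankrd1 (0.99), Ajuba (0.90), Cyr61 (0.73) and Amotl2 (0.72). The antioxidant and metallothionein list went both ways. Its median was 0.15 (percentile 98.7), with 17 of 27 above the median gene, Mt2 the highest, and Mt1 (3.18), Gsr (2.91) and Srxn1 (2.37) next. The last pair act on glutathione and peroxiredoxins.

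Medians below like lists were found in 3 programmes. All 37 measured nuclear genes of oxidative phosphorylation lay below the median gene, with a median of -0.41 (percentile 0.13), and the lowest were Atp5k (-0.84), Sdhd (-0.81), Atp5e (-0.72) and Ndufa2 (-0.61). The central 95% of random lists matched to these genes also lay below the median gene, from -0.35 to -0.09. Of the beta and gamma crystallins, which make up much of the fibre cell protein, 12 of 14 lay below the median gene, with a median of -0.40 (percentile 2.36). Crygf (-1.34), Crygd (-1.01) and Crygb (-0.87) were the lowest, and Crybb3 was higher (0.69). All crystallin genes together took 15.9% of wild-type and 14.2% of knockout UMIs in the non-fibre clusters, and 35.3% and 20.5% in all retained cells, where the list's median in CPM was -0.95 against -0.25 in the non-fibre clusters. Free RNA from fibre cells, which differed in number between the libraries, was not separated from this fall. The MHC and complement list had a median of -0.43 (percentile 2.10), with members on both sides, namely Cd59a (-0.90), B2m (-0.75), H2-K1 (0.23) and H2-Q4 (1.09) among those with the largest ratios. Among the 14 alternatives of the processing, those of scaling shift a list and its random lists alike and could move none. Of the 15 lists outside their random lists, 7 stayed outside in all 14. The crystallin list did so in 7 of 14, the MHC and complement list in 8, the YAP list in 9, the insulin and PI3K list in 11, the antioxidant and metallothionein list in 12, and the S phase, FGF and ERK and BMP lists in 13 each. In all retained cells the median of the antioxidant and metallothionein list was -0.12 relative to the median gene, inside its random lists.

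**Figure D4:**
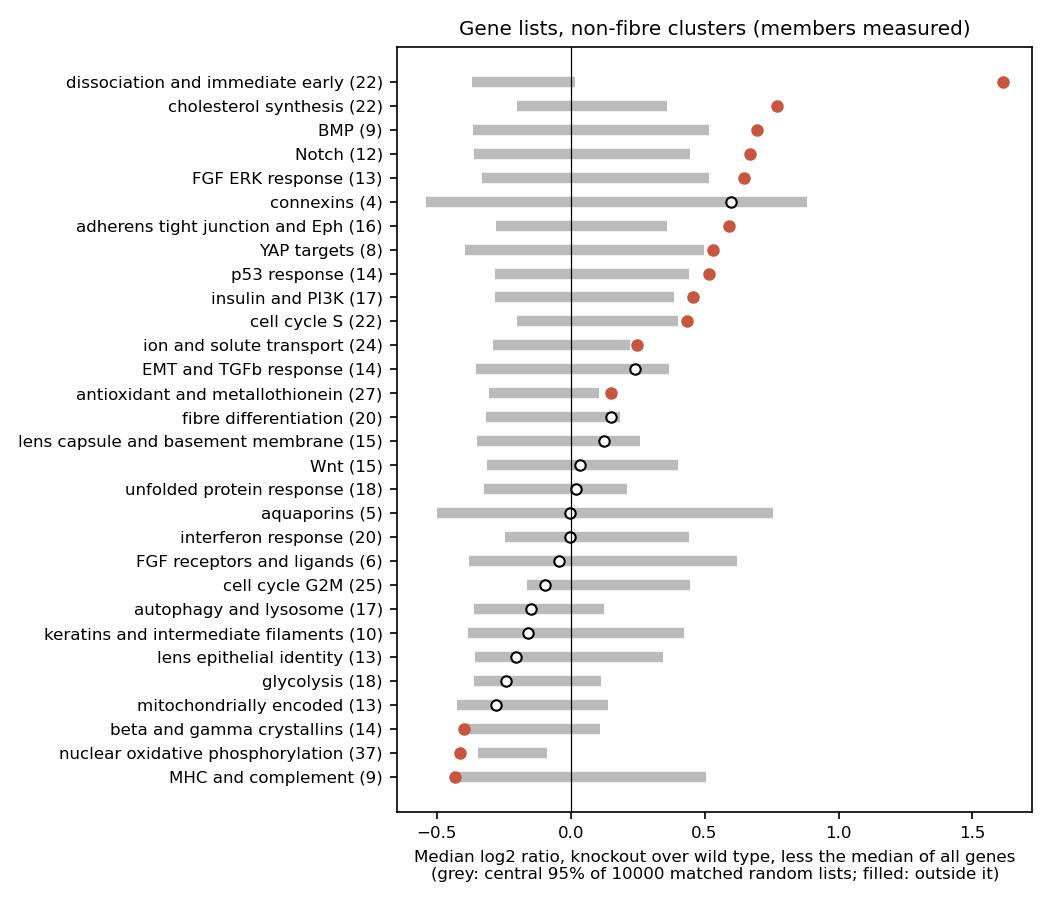
Median log2 ratio of each programme list relative to the median gene (horizontal axis, filled points outside the central 95% of 10000 random lists, open points inside, grey bars for that central 95%), with the number of measured members after each name. The list of dissociation and immediate early genes lies at 1.61 and the list of nuclear oxidative phosphorylation genes at -0.41.

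The other lists lay inside the central 95%. The median was -0.20 over 13 genes of lens epithelial identity, with Pax6 at 501 and 480 CPM in the wild-type and knockout libraries. It was 0.15 over 20 genes of fibre differentiation, 0.02 over 18 of the unfolded protein response, 0.24 over 14 of epithelial-mesenchymal transition and TGFβ response and 0.12 over 15 of the lens capsule and basement membrane. It was -0.24 over 18 glycolysis genes, -0.28 over 13 mitochondrially encoded genes, -0.00 over 20 interferon response genes, 0.03 over 15 Wnt genes, -0.16 over 10 keratin and intermediate filament genes and -0.15 over 17 autophagy and lysosome genes. The 2 alpha crystallins had a median of -0.26 and the 2 genes known to vary between mouse strains, Nnt (-1.13) and Bfsp2 (-0.19), one of -0.66, with too few members for random lists.

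Marker lists of other cell types were mostly unmeasured. No lymphocyte or erythroid marker reached 20 UMIs, and 1 marker each did for neutrophils or mast cells (0.15), photoreceptors (-0.28), neurons (-0.51) and muscle (-0.13). Medians were 0.19 over 3 macrophage markers, 0.38 over 4 fibroblast, 0.01 over 4 endothelial or pericyte, 0.64 over 4 pigmented epithelium, 0.42 over 2 ciliary epithelium, 0.29 over 7 Müller glia, -0.17 over 5 corneal epithelium, 0.42 over 2 corneal endothelium and -0.56 over 3 Schwann cell markers, all inside the central 95% where random lists could be drawn. The lens epithelial markers had -0.41 over 9 genes and the lens fibre markers -0.20 over 12, both inside it. The cycling markers had -0.26 over 12 genes, at percentile 2.09 of like lists.

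The libraries also differed in the sex of the cells. No Y-linked UMI was found in any of the 1821 wild-type cells, against 360 in the knockout library, where 205 of 2104 cells (9.74%, 8.51% to 11.1%) had a Y-linked UMI and no Xist UMI. In the non-fibre clusters, Xist, the RNA of the inactive X chromosome, had a log2 ratio of -0.95 (-0.98 to -0.92), its antisense partner Tsix -2.14, a count that is uncertain because the use of strand is not stated, and the Y-linked gene Ddx3y had 0 and 214 UMIs. The sex-linked list had a median of 3.46 over 5 genes with the Y-linked genes at their bounds.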

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

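The test of sex on the immediate early genes, the test of the immediate early state on Aqp1, and the whole-set tests of the 8-fold lower genes were written before their results were seen, and the heat shock, handling, cluster, free RNA, Rnaset2b alone and Pacs2 with Rnaset2b tests only after.

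Aqp1 was also higher in barcodes that the filter or the doublet calls had removed from the main comparisons. They come from the same libraries, and the alternatives without the barcode filter or with doublet calls kept drew on them. Aqp1 stood at 134 CPM in the 505 removed knockout barcodes (84 UMIs, 107 to 166) against 30.1 CPM in the 692 removed wild-type barcodes (37 UMIs, 21.2 to 41.6). The removed barcodes also differed in content, with the crystallin gene Crygc at 15867 CPM in the wild type and 6385 CPM in the knockout. For the rise of Aqp1 in the retained cells, 3 technical explanations were set against the genotype. A different mix of clusters would leave no difference within clusters, but the lowest log2 ratio of Aqp1 CPM in a non-fibre cluster with enough cells of both libraries was 1.33, with a lower bound of 0.93. Such clusters held only 199 of the 1892 knockout non-fibre cells, so the other knockout cells are not covered. Values were also centred within each library before clustering, so cells of the same cluster can still differ between libraries. In cluster 4, for example, Fos was at 595 CPM in wild-type and 5471 CPM in knockout cells. A different mix of cell states within a cluster is therefore not tested by these ratios. Free RNA would put Aqp1 into every type of cell alike, but the knockout fibre side had 13.6 CPM against 290 CPM in the non-fibre clusters. Cells matched on their share of immediate early UMIs (376 per library) still had a log2 ratio of Aqp1 CPM of 1.60, with a lower bound of 1.39. An effect of the genotype stays open as a hypothesis, as do strain, litter and any other difference between the pooled animals, while for sex the log2 ratio of CPM was 1.80 both in knockout cells with Xist and no Y-linked UMI and in all knockout cells of the non-fibre clusters.

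The rise of immediate early genes in the knockout library, with a median log2 ratio of CPM of 1.76, is what different handling of the knockout cells would give, and what the genotype could give too. These cannot be told apart, since each genotype is given as 1 combined matrix without replicate numbers. The sex of the animals as the whole cause is argued against by knockout cells with an Xist and no Y-linked UMI, in which the median was 1.74. A heat shock response cannot be decided, because the 5 heat shock members of the list had a median of -0.0188 relative to the median gene and ran from -6.39 for Hspa1b to 1.13 for Dnajb1.

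Of the genes at least 8-fold lower in the knockout library by the bound nearest to 1, 8 were weighed as well, a limit chosen after their values were seen. Of these 8, 2 had a near-identical copy (25%, against 89 of 869 matched genes). The search covered only the last 600 bases of annotated transcripts at 95% identity or more. Shared reads with less similar or unannotated copies were therefore not tested for the others. Summed with copies, the median log2 ratio of CPM of the 8 was -5.24, with counts under 3 UMIs set to 3. Adding copies changes only the 2 genes that have one, so this median could not decide the question. For Rnaset2b alone the sum with Rnaset2a gave a log2 ratio of CPM of -0.21, while Rnaset2a itself rose to a relative log2 ratio of 0.35 (0.27 to 0.44), so a shift of reads between the copies, as a sequence variant could cause, is a candidate explanation there. Another cell state in the wild-type library stays open for most of them. The planned limit could be read in only 3 of 8, those with at least 20 wild-type UMIs on the fibre side (median log2 ratio of CPM -3.74). Pacs2 and Rnaset2b were lower there too. Their higher log2 ratio of CPM was -3.74, with both upper bounds at or below -2.88. For these 2 genes that argues against a state found only outside the fibre side. They were picked after their values were seen, and free RNA was not separated. Strain variants were not tested.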

How the results depend on the processing

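No paired analysis was possible because each genotype was given as 1 combined matrix with no replicate number on its cells, and no library could be left out. The weighting to clusters with 20 cells of both libraries, the restriction to knockout cells with Xist and no Y-linked UMI, and the clusterings on thinned cells or without sets of genes were chosen after seeing the data. The planned weighting of all clusters to equal shares was not run, because most lacked cells of 1 library. Aqp1 stayed higher in the knockout library under all alternatives run for it. The log2 ratio of Aqp1 CPM, 1.80, moved to 1.66 with median-of-ratios scaling and 1.64 as a mean over cells. It was 2.30 in all retained cells and 2.37 with the cluster weighting, over 3 clusters. The 1145 genes at least 2-fold higher became 1904 in all retained cells, where the median of all genes was 0.47. With the cluster weighting, which tested 5843 genes, they became 582. The 144 genes with a ratio of 1/2 or less became 226 with median-of-ratios scaling and 218 with the cluster weighting. They became 236 at a minimum of 50 UMIs and 77 at a minimum of 200 UMIs, and the minimum changes how many genes are tested. The share of cells in clusters mostly of 1 library, 84.0%, was 44.4% without the barcode filter, 56.1% with the stricter filter, 82.5% with doublet calls kept, 80.2% without centring, 72.6% at resolution 0.3, 72.8% without the immediate early list, 38.7% in thinned cells and 0% without genes that differ 2-fold, which takes out the split by construction. The difference in the share of cells with G2M transcripts, 0.758 percentage points, was 3.09 with at least 1 UMI, 1.70 with doublet calls kept and 1.29 with the stricter filter. The cause was not tested for these other than where stated. A value relative to the median gene cannot change under the alternatives of scaling. Most named genes were also picked for their extreme ratios in these data, so a kept direction says little of them. Of 446 values of named genes and list medians relative to the median gene under alternatives, 445 kept their direction. The exception was the median of the antioxidant and metallothionein list, which went from 0.15 to -0.12 in all retained cells. In CPM the exception was the MHC and complement list (-0.29 to 0.21), which stayed below the median gene there (-0.26). The number of lists outside their random lists went from 15 to 11 with the cluster weighting. Of the 15, the crystallin, FGF and ERK, antioxidant and metallothionein, MHC and complement, BMP, and insulin and PI3K lists then lay inside theirs. The 11 therefore include lists that lay inside in the main run. In CPM and shares of cells, 27 of 453 values moved beyond the counting interval or the spread of random lists. In log2 ratios of CPM, the cluster weighting took Emp1 from 6.02 to 2.79, Hspa1b from -6.25 to -3.12 and 4930481A15Rik from -3.58 to -1.53. It took Rflna from -3.21 to -1.67 and Rnaset2b from -4.81 to -7.13. The difference in cells with G2M transcripts was -0.0126 percentage points without thinning. Genes with few UMIs in 1 library, such as Htr1d or Iigp1, have intervals spanning many-fold ranges, which depth limits.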

Other observations

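The test of a shared axis was chosen only after its clusters had been seen. Within each library, part of the differences between clusters ran alike, which the comparison of genotypes does not show. In the wild type, cluster 4 against cluster 5 had higher R3hdml (log2 contrast of CPM 4.29, at a pseudocount of 20 CPM), Aldh3a1 (3.95), Igkc (3.16), Ptgds (2.42) and Gja1 (2.06), the gene of connexin 43. It had lower Nnat (-4.12), the Notch targets Hes5 (-2.99) and Hey1 (-1.59), Ccdc80 (-2.68), Id1 (-2.20) and the cyclin gene Ccnd1 (-1.78). In the knockout, cluster 3 against cluster 1 had higher R3hdml (3.53), Aldh3a1 (2.77), Igkc (3.16), Ptgds (2.74) and Gja1 (1.74), and lower Nnat (-3.40), Hes5 (-1.46), Hey1 (-1.58), Ccdc80 (-2.70), Id1 (-2.62) and Ccnd1 (-3.12). Other genes went opposite ways. From cluster 4 to cluster 5 of the wild type, Nfkbia went from 48.7 to 354 CPM, Mt1 from 18.6 to 177 CPM and Ccl2 from 25.4 to 46.4 CPM, whereas from cluster 3 to cluster 1 of the knockout Nfkbia went from 1107 to 182 CPM, Mt1 from 2357 to 624 CPM and Ccl2 from 2662 to 396 CPM. All these genes were chosen after their values were seen.

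A candidate explanation is that both libraries share part of a gene programme of the epithelium. Across 4098 genes with a mean of at least 20 CPM, which are not independent replicates, the contrasts had a Pearson r of 0.536 and a Spearman rho of 0.496, and 90 of 98 genes that were 2-fold different in both had the same sign. With wild-type cluster 2 in place of cluster 4, the Pearson r was higher, at 0.731. Cluster 4 is therefore not singled out as the counterpart of knockout cluster 3. The position of the cells in the lens was not measured. Along this axis Aqp1 in the wild type was at 147 CPM in cluster 5, 69.7 CPM in cluster 4 and 26.3 CPM in cluster 2. In the knockout it was at 289 CPM in cluster 1 and 310 CPM in cluster 3. No test of that difference between genotypes was run.

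Prm1 UMIs occurred in the knockout library on both sides of the clustering. They were found in 14.6% of non-fibre cells and 22.6% of fibre-side cells (7.30% and 11.4% after thinning to 3000 UMIs), against 0 of 1288 and 0 of 533 wild-type cells, and 28 UMIs were in removed knockout barcodes. The labels do not describe the knockout construct, so whether the UMIs come from the Prm1 locus is not known.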
